A study of Vitis vinifera with 18 samples.

How the data were processed

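Small RNA libraries of grapevine (Vitis vinifera) callus from anther culture were compared. There were 18 libraries, in 6 groups of 3 biological replicates. The groups combine 2 cultivars, Cabernet Sauvignon (CS) and Sangiovese (SG), with 3 tissues. The tissues were embryogenic callus (EC), non-embryogenic callus (NEC) and undifferentiated callus sampled at 40 days (40D). EC and NEC were told apart under a stereomicroscope 4 months after the cultures were started, per the labels. The labels call the libraries of a group biological replicates and do not say whether each came from a separate culture, so the p-values measure the spread between these libraries, part of which can be technical.

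The deposited files give, for each library, a list of distinct sequences of 18 to 50 nt and the read count of each, per the labels and the values themselves, which were whole numbers. CASAVA 1.8.2 and cutadapt 1.9 are named in the submitters' processing notes. An aligner, a genome build and the tool that collapsed the reads are not given in the sources used here. No molecular identifiers are described, so reads are not independent molecules, and intervals and floors cover counting error only. Total depth per library, in units of 1e+06 reads, was 7.25 to 21.2, of which 5.43 to 16.5 were of 18 to 30 nt. At that depth a group without a read was treated as holding fewer than 3 reads over its 3 libraries.

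Reads of 18 to 30 nt were used for the size classes. The log2 ratio of 24 nt to 21 nt reads and the shares of 21, 22 and 24 nt reads were computed per library. So was the share of reads that lie within 8 reference sequences of structural RNA (2 rRNA and 6 tRNA). The references hold 5S and 5.8S rRNA and the start of 6 tRNAs, and no large rRNA, so this share is a lower limit of breakdown products. Tissues were compared over both cultivars with an exact two-sided permutation test that permuted the labels within each cultivar (400 arrangements, smallest possible p 0.005). Benjamini-Hochberg adjustment covered the 8 tests of size classes. Within 1 cultivar, 3 against 3 libraries cannot give a p below 0.1.

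For miRNA families, tags of 19 to 24 nt were summed where they started within 1 nt of a reference mature sequence and had at most 1 substitution over an overlap of at least 18 nt. A tag that matched several families went to the nearest. The 34 families and their 7 lists were fixed before the data were examined. The auxin list held miR160, miR167, miR390, tasiARF (the small RNAs that miR390 triggers against auxin response factors) and miR393. The development list held miR156, miR159, miR164, miR166, miR169, miR171, miR172, miR319, miR394 and miR396. The nutrient list held miR395, miR397, miR398, miR399, miR408, miR827 and miR2111, and the silencing list miR162, miR168 and miR403. The list of phased siRNA triggers held miR482, miR828 and miR858, and the list of other families miR535, miR845, miR3627 and miR3634. As controls thought absent from grapevine, the rice family miR528 and the animal family let7a were included. A table of gene names for the assembly ASM3070453v1 listed loci for 29 of the 32 families looked up. Reads were not placed on a genome, so reads of loci that share a mature sequence were summed in 1 family.

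Counts were tested with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with the 6 groups in 1 fit. filterByExpr kept 28 families. The library size was the family total with TMM factors, so that a change of a family is relative to the others. With so few families these factors can follow 1 abundant family. In a separate fit, each distinct sequence of 20 to 24 nt kept by filterByExpr (34827 tags) was tested, with the total of 18 to 30 nt reads as library size and TMM factors over the tags. A call is an adjusted p under 0.05 (Benjamini-Hochberg, over all families or tags of a comparison). For the lists, families were also adjusted over the list alone.

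Named families were, by a rule fixed before the data were examined, those past 0.05 in a comparison of EC with NEC (at most 20 per comparison) and the 10 with the smallest adjusted p elsewhere, with members that did not pass given as examples. Named tags were the 5 with the largest rise and the 5 with the largest fall per comparison of EC with NEC. They had to pass 0.05, show no overlap between the 3 and 3 libraries (which chance gives for 10% of tags) and average at least 20 reads per 1e+06 reads (rpm) over the 18 libraries. Folds with 1 to 3 reads in a group are given with a 95% counting interval.

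The matching and the tests were checked on simulated data. All 282 sequences made from the references, with a start within 1 nt and at most 1 substitution, were assigned to the right family (100%), those with 2 substitutions were rejected (100%), and 0 of 100000 random sequences matched. The permutation test called 4% of unchanged and 100% of shifted simulations, and its test of the difference between cultivars 6% of unchanged ones. With counts drawn for the 28 families of CS EC against CS NEC, edgeR recovered 2 of 2 families changed 2-fold, 0 of 2 changed 4-fold and 2 of 2 changed 8-fold, and called 0 of 22 unchanged ones. For the 34827 tags of that comparison, it recovered 1.49% of 67 tags changed 2-fold, 31.3% of 67 changed 4-fold and 75.8% of 66 changed 8-fold, and called 1 of 34627 unchanged tags. With 2 families per fold, the family counts give no rate of recovery. Apart from the few changed features, all libraries were drawn from the same means. The simulation therefore cannot show how the scaling behaves where most families change.

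Alternatives fixed before the data were examined were DESeq2 1.42.0 with its own size factors, total reads of 18 to 30 nt as library size without TMM, no filter on low counts (for tags, at least 3 reads in 3 libraries), exact matches only, the sequencing lane as a covariate, the replicate number as a block, and each library left out in turn. For size classes they were distinct sequences in place of reads, removal of the 20 most abundant tags, and removal of structural RNA reads. Matching of tags that start within 3 nt, structural matches with 1 substitution, and removal of abundant tags together with reads within 1 substitution of structural RNA, were added after the data were seen. The lane, 7 or 8, comes from the names of the deposited files. Each pair of libraries within a group differed by more than sampling noise (chi-square per degree of freedom 2.84 to 20.9). Planned 5 kb windows of 24 nt reads needed a genome sequence and were not run. Reads over 30 nt entered only the closing observations. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pyarrow 21.0.0, matplotlib 3.10.9 and the R package data.table (1.17.8) were used.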

Results

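Small RNAs were sequenced from grapevine callus that had formed embryogenic structures (EC), from callus of the same age that had not (NEC) and from undifferentiated callus at 40 days (40D), in Cabernet Sauvignon (CS) and Sangiovese (SG). Each of the 6 groups had 3 libraries. Total depth per library, in units of 1e+06 reads, was 7.25 to 8.71 in CS EC, 12.3 to 19.7 in CS NEC and 9.87 to 18.2 in CS 40D. In Sangiovese it was 12.8 to 21.2 in EC, 15.3 to 17.4 in NEC and 8.60 to 10.0 in 40D. Over tags of 20 to 24 nt, the leading dimension of a multidimensional scaling (31.8% of the variance) separated the cultivars and the next one (24.8%) separated EC from the other tissues.

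The first comparison asked whether the size classes of small RNA differ between callus with and without embryogenic competence. In both cultivars 24 nt small RNAs, the class that guides DNA methylation at transposons and repeats in plants, made up a far larger part of the reads in EC. Their share of 18 to 30 nt reads was 25.3% ± 5.20 (SD, n = 3) in CS EC against 7.47% ± 0.187 in CS NEC, and 32.8% ± 1.27 in SG EC against 8.15% ± 0.238 in SG NEC. The 21 nt class, the length of most miRNAs, moved the other way: 22.2% ± 3.40 in CS EC against 35.5% ± 2.91 in CS NEC, and 27.0% ± 1.23 against 33.3% ± 2.28 in Sangiovese. A single tag that matched no family, CCCAGTCCCGAACCCGTCGGC, was 17.8% ± 1.94 of reads in CS NEC and 12.6% ± 0.531 in SG NEC, and so a large part of that class. The structural references used here hold no large rRNA, so whether this tag is an rRNA fragment was not tested. The 22 nt class was at 5.96% ± 0.218 in CS EC against 7.29% ± 0.510 in CS NEC, and at 5.14% ± 0.140 against 8.21% ± 0.145 in Sangiovese. Fragments of rRNA and tRNA made up 1.46% ± 0.0996 of reads in CS EC, 2.08% ± 0.250 in CS NEC, 1.04% ± 0.0700 in SG EC and 2.58% ± 0.151 in SG NEC.

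The log2 ratio of 24 to 21 nt reads was higher in EC than in NEC by 2.37, by 2.42 in Cabernet Sauvignon and by 2.31 in Sangiovese, and in each cultivar every EC library lay above every NEC library. The exact permutation test over both cultivars gave p = 0.005, the smallest it can give, and 0.00571 after adjustment. The shares of 24 nt (21.2 percentage points higher), 21 nt (fell by 9.83), 22 nt (fell by 2.20) and structural RNA reads (fell by 1.08) gave the same p and adjusted p. Without the 20 most abundant tags the 21 nt share fell by 1.72 and the log2 ratio differed by 1.78, each with an exact permutation p of 0.005. Within 1 cultivar the exact p was 0.1, the smallest possible. In Cabernet Sauvignon EC was sequenced on lane 8 and NEC on lane 7, so lane and tissue cannot be told apart there. Within lane 7, SG EC (2 libraries) lay 24.7 percentage points above SG NEC in the 24 nt share and 2.34 above it in the log2 ratio.

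**Figure D1:**
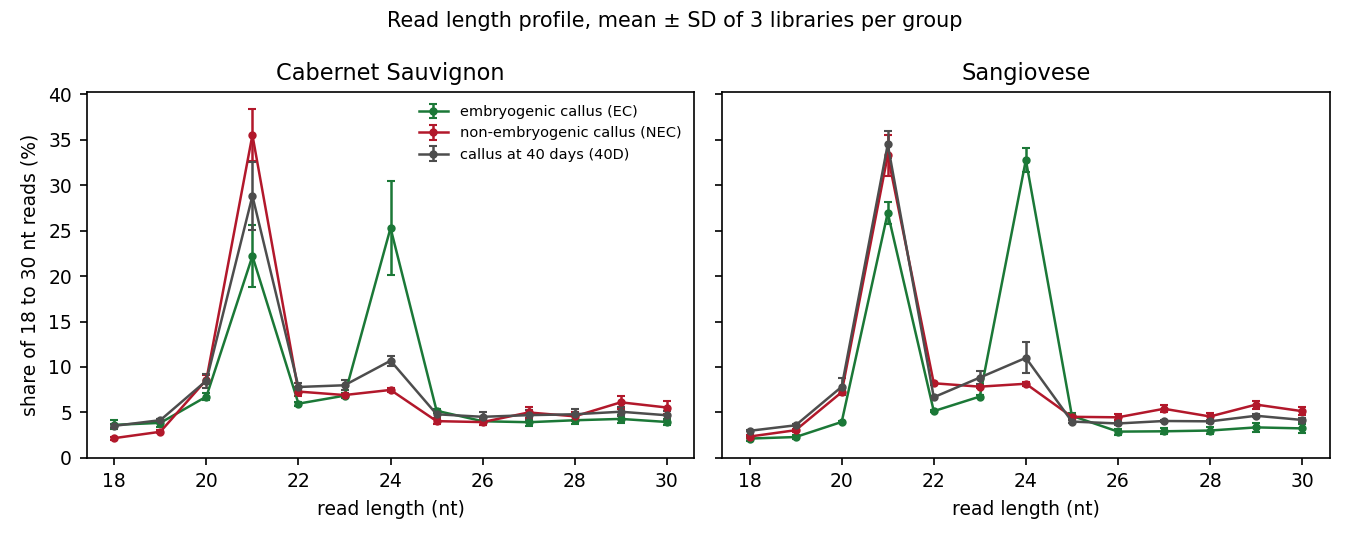
Share of 18 to 30 nt reads (y, percent) by read length (x, nt) in each cultivar, with points and bars for the mean and SD of 3 libraries and colours for the tissues. EC has a peak at 24 nt, at 25.3% in Cabernet Sauvignon and 32.8% in Sangiovese, where NEC lies at 7.47% and 8.15%.

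Callus at 40 days lay between NEC and EC in this ratio, and closer to NEC. The log2 ratio was 0.18 ± 0.48 (SD, n = 3) in CS EC, -1.42 ± 0.24 in CS 40D and -2.25 ± 0.094 in CS NEC. In Sangiovese it was 0.28 ± 0.061 in EC, -1.66 ± 0.28 in 40D and -2.03 ± 0.11 in NEC. EC exceeded 40D by 1.77 and NEC fell by 0.60 relative to 40D, each with an exact permutation p of 0.005 and an adjusted p of 0.00571. Between NEC and 40D the difference was -0.20 without the 20 most abundant tags (exact permutation p = 0.01) and -0.31 over distinct sequences (p = 0.015), and lane cannot be told apart from tissue, with all NEC libraries on lane 7 and all 40D libraries on lane 8. In Cabernet Sauvignon EC and 40D shared lane 8, and the 24 nt share differed there by 14.6 percentage points. The EC to NEC difference in the log2 ratio differed between the cultivars by -0.11 (exact permutation p = 0.79, adjusted p = 0.79), and CS EC replicate 1 decided this value, which was -0.38 without it (exact permutation p = 0.01).

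**Figure D2:**
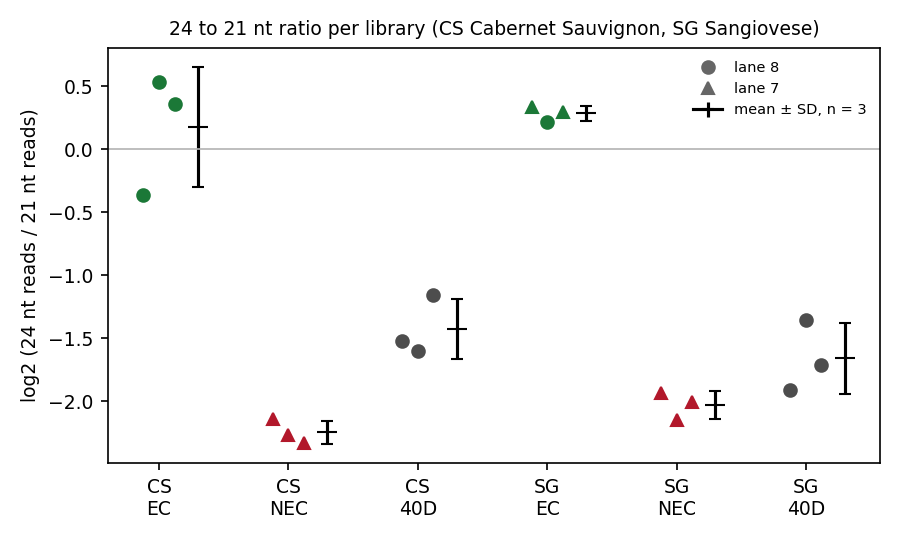
Log2 ratio of 24 to 21 nt reads (y) in each of the 18 libraries by group (x), with triangles for lane 7, circles for lane 8, and black bars for the mean ± SD of 3 libraries. All EC libraries lie at or above -0.36 and all NEC libraries at or below -1.93.

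The second comparison asked which conserved miRNA families distinguish EC from NEC. EC held far more reads of miR156, the regulator of SPL transcription factors and of juvenile growth. Its level, in reads per 1e+06 reads of 18 to 30 nt (rpm), was 1134 ± 240 (SD, n = 3) in CS EC against 124 ± 4.89 in CS NEC, and 2305 ± 389 against 181 ± 47.6 in Sangiovese, with log2 fold changes of 3.87 (SE 0.34, edgeR adjusted p = 1.09e-07) and 3.82 (SE 0.34, adjusted p = 6.29e-08). The related families miR319 and miR159, which target TCP and GAMYB transcription factors, rose as well, by log2 2.84 and 2.79 in Cabernet Sauvignon and 4.02 and 2.39 in Sangiovese. The strongest fall was that of miR393, the regulator of the TIR1 and AFB auxin receptors, from 185 ± 57.9 to 1.44 ± 1.25 rpm in Cabernet Sauvignon and from 388 ± 31.7 to 12.9 ± 13.7 in Sangiovese. Its log2 fold changes were -6.28 (SE 1.06, adjusted p = 6.28e-05) and -4.64 (SE 0.92, adjusted p = 0.000469), and -5.63 and -6.90 without CS EC replicate 1 or 3 and -6.13 without SG EC replicate 3. With lane as a covariate the Cabernet Sauvignon value was -1.93 and did not pass (adjusted p 0.216). In that fit only SG EC, the group with libraries on both lanes, sets the lane term. Its replicate 2, alone on its lane, held 18 miR393 reads, against 109 and 222 in replicates 1 and 3. The changed value therefore rests on 1 low-count library of the other cultivar and cannot tell a lane effect from the spread between libraries.

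Of the 8 development families tested, 6 rose and 1 fell in Cabernet Sauvignon, and 4 rose in Sangiovese while 4 did not pass (adjusted over the list alone, the counts were also 6 and 1, and 4). The members that rose in both were miR156, miR159, miR319 and miR394, a family that targets an F-box gene of the shoot meristem, with log2 fold changes of 7.16 (SE 0.84) in Cabernet Sauvignon and 3.52 (SE 0.77) in Sangiovese. It had 0 to 3 reads in a CS NEC library and 1 to 5 in an SG NEC library, and the values were 8.41 without CS NEC replicate 2 and 4.37 without SG NEC replicate 3. In Cabernet Sauvignon miR171, which targets GRAS transcription factors of the meristem, rose by log2 2.25 (1.26, adjusted p 0.0585, under DESeq2 and 1.16, adjusted p 0.216, with exact matches) and miR396, which targets growth-regulating factors, fell by 1.37. Their Sangiovese values of 1.05 and -0.90 did not pass (adjusted p 0.0539 and 0.0635). Family miR166, which targets HD-ZIP III transcription factors, rose by log2 2.33 in Cabernet Sauvignon (adjusted p = 2.82e-07) and was at 0.26 in Sangiovese. With reads that start up to 3 nt from the reference its Cabernet Sauvignon change was 0.23 (adjusted p 0.410), since 81.9% ± 4.10 of miR166 reads in CS NEC started 2 nt upstream. The list's miR164, a regulator of NAC genes, had 0.64 in Cabernet Sauvignon and 0.88 in Sangiovese and passed in neither.

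In the auxin list, 3 of 5 families rose and 1 fell in Cabernet Sauvignon, and 2 rose and 2 fell in Sangiovese (adjusted over the list alone, the counts were also 3 and 1, and 2 and 2). The tasiARF small RNAs rose by log2 3.63 (SE 0.41) and 2.60 (SE 0.38), and their trigger miR390 by 1.22 (SE 0.45) and 1.83 (SE 0.46). With exact matches only, tasiARF did not pass in either cultivar (0.90, adjusted p 0.501, and 1.85, adjusted p 0.0629). The Cabernet Sauvignon call of miR390 was lost under DESeq2 size factors (0.22), under total reads (0.56) and in 4 of the 6 runs without 1 library (0.91 at the lowest), and its sign turned with exact matches (-0.23). In Cabernet Sauvignon miR160, which targets auxin response factors, had 14 reads in EC and 3 in NEC, a ratio of 6.40 (95% counting interval 1.79 to 34.7), and its call was lost without CS EC replicate 1 (ratio 4.26). In CS NEC, 2 of the 3 reads were in replicate 2. In Sangiovese miR167, also directed at auxin response factors, fell by 1.41.

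Among the 6 nutrient families, 3 rose and 2 fell in Cabernet Sauvignon, and 4 rose and 2 fell in Sangiovese (adjusted over the list alone, also 3 and 2, and 4 and 2). The sulfate-responsive miR395 rose by log2 4.32 (SE 0.94) and 5.26 (SE 0.92), miR397, which targets laccases, by 2.26 and 2.04 (0.78, not passed, with exact matches in Cabernet Sauvignon), and miR408, which targets copper proteins, by 1.23 and 1.06. The miR395 value in Cabernet Sauvignon was 2.62 without CS EC replicate 1, which held 88 of the 106 reads in EC, and 4.99 without CS NEC replicate 1. In Sangiovese it was 4.60 without SG EC replicate 3 and 5.95 without SG NEC replicate 2. In Cabernet Sauvignon miR408 did not pass under DESeq2 (0.24), under total reads (0.53), with no filter on low counts (0.61) or with lane as a covariate (1.03), and its sign turned with exact matches (-0.22). The phosphate-responsive miR399 rose by 3.54 (SE 0.77) in Sangiovese (4.89 without SG NEC replicate 2). Both miR398, which targets copper superoxide dismutases, and miR827, a family of phosphate homeostasis, fell, by 1.19 and 1.36 in Cabernet Sauvignon and 0.93 and 1.02 in Sangiovese. The miR398 call in Sangiovese was lost without SG EC replicate 2 (-0.84), and that of miR827 in 5 of the 6 runs without 1 library in either cultivar (-1.06 and -0.75 at the weakest). The most abundant tags of miR827 (2222 reads over all libraries) and miR399 (72 reads) had 1 substitution. Neither family was kept with exact matches, and the table of gene names listed 0 loci for miR827.

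The silencing families, which target DCL1 (miR162), AGO1 (miR168) and AGO2 (miR403), had 1 call in the 2 cultivars in the family fit. In Cabernet Sauvignon their log2 fold changes of -0.74, -0.39 and 0.086 did not pass. In Sangiovese 1 of 3, miR162, fell by 1.81 (adjusted over the list alone, also 1). In the fit over tags, the most abundant tags of miR162, miR168 and miR403 fell in both cultivars. They were at log2 -1.95, -1.70 and -1.19 in Cabernet Sauvignon (edgeR adjusted p 3.50e-06, 2.07e-06 and 0.000201). In Sangiovese they were at -1.98, -0.62 and -0.82 (adjusted p 1.39e-06, 0.0214 and 0.00292). The fits differ in their scaling, so the few family calls do not show that these families were unchanged. Of the 2 phased siRNA triggers tested, miR482, directed at disease resistance genes, rose by 1.99 in Cabernet Sauvignon (0.42, adjusted p 0.501, with exact matches) and miR858, directed at MYB genes, fell by 2.06 in Sangiovese (-2.74 without SG EC replicate 1), so that 1 of 2 passed in each (adjusted over the list alone, also 1). Of the 4 other families, miR535 rose by 1.67 (0.67, not passed, under DESeq2 and 0.14, not passed, with exact matches) and 1.21 and miR845, which matches the primer binding site of retrotransposons, by 3.80 and 2.31 (3.28 without SG NEC replicate 1). In Cabernet Sauvignon miR845 rested on 15 reads against 2, a ratio of 10.3 (95% counting interval 2.39 to 92.7). Its most abundant tag, with 73 reads over all libraries, was 24 nt long with 1 substitution, and miR845 was not kept with exact matches. The grapevine family miR3627 fell by 3.62 in Sangiovese (-5.29 and -2.81 without SG EC replicate 1 or 2), so that 2 of the 4 rose in Cabernet Sauvignon and 2 rose and 1 fell in Sangiovese (adjusted over the list alone, the same counts). The very abundant miR3634 did not pass in either cultivar, but the family TMM factors followed it, which largely fixed that outcome. In the fit over tags its most abundant tag was at log2 -1.37 (edgeR adjusted p = 5.23e-05) in Cabernet Sauvignon and -0.37 (adjusted p 0.176) in Sangiovese. The control miR528 had 0 reads, which allows fewer than 3 in a group, and let7a had at most 2 reads in a library.

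Over the 28 families, edgeR called 15 higher and 4 lower in Cabernet Sauvignon and 12 higher and 7 lower in Sangiovese. In both cultivars 11 families rose, where independent lists would share 6.43, and 3 fell, where they would share 1, with 0 in opposite directions. The TMM factors shifted all families by log2 0.66 in Cabernet Sauvignon and 0.16 in Sangiovese relative to total reads, and DESeq2 size factors by -0.34 and -0.14, with the splits then 10 higher and 9 lower, and 12 and 11. No called family turned under these scalings, and total reads gave 13 higher and 7 lower in Cabernet Sauvignon. TMM held the abundant miR3634 nearly constant (-0.068 and -0.052), so the family changes are close to changes relative to it. In the fit over tags, the most abundant tags of miR156, miR159 and miR319 rose by less than these families. They rose by log2 2.90, 1.68 and 1.71 in Cabernet Sauvignon and by 3.72, 2.13 and 3.12 in Sangiovese. With exact matches only, 8 of the 16 Cabernet Sauvignon calls that could be tested kept direction and call and 2 turned, and 12 of 16 kept them in Sangiovese. With lane as a covariate 12 families were called in Cabernet Sauvignon, all higher in EC, and within lane 7 alone 12 were higher and 5 lower in Sangiovese.

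**Figure D3:**
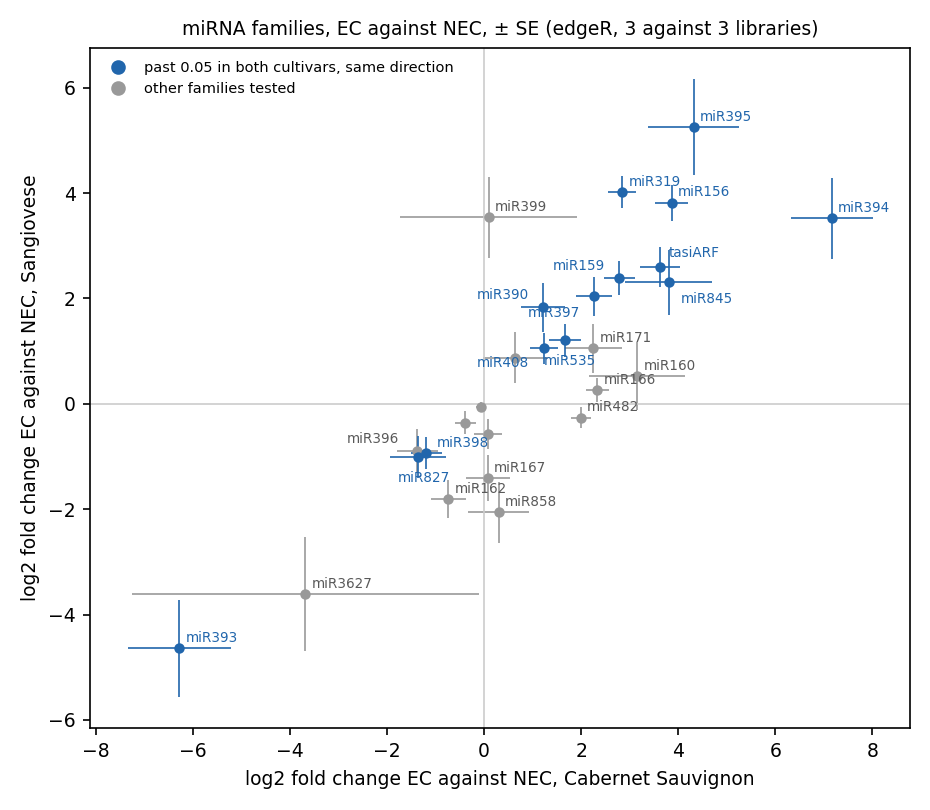
Log2 fold change of each of the 28 miRNA families between EC and NEC in Cabernet Sauvignon (x) and Sangiovese (y), with bars for the SE of edgeR's fit to 3 against 3 libraries. The 14 families in blue pass 0.05 in the same direction in both cultivars (in Cabernet Sauvignon miR390, miR408 and miR535 do not pass under DESeq2). Of these, miR393 fell the most in both, and the largest rise was of miR394 in Cabernet Sauvignon and of miR395 in Sangiovese.

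The third comparison took every distinct sequence of 20 to 24 nt. Among the tested tags, rises concentrated in those of 24 nt: 42.0% of the 19516 tested rose in CS EC against CS NEC and 67.7% in Sangiovese, while 12.5% and 11.9% fell. The filter keeps a tag that is high in the 3 libraries of 1 group only. A tag found mainly in EC of 1 cultivar thus enters through that group. The shares by length, and the gap between the cultivars, are therefore partly set by the filter. Among 21 nt tags, 17.3% rose and 35.0% fell in Cabernet Sauvignon, and 23.0% rose and 34.9% fell in Sangiovese. Among the tags with the largest rises in Cabernet Sauvignon were 2 forms of miR166, TTCGGACCAGGCTTCATTCCCC (log2 5.35, 1722 ± 732 rpm in EC against 26.6 ± 3.37 in NEC) and TTCTCGGACCAGGCTTCATTCCCC (5.27, and 4.93 in Sangiovese). The others were TCCCGGACAATGACGTGACAT (5.48), TGAAGAACATCCAAGAAGCCT (5.27) and CAAGCCAAGTGTAGAAGTCCT (4.96), which matched no family. In Sangiovese TGAAGAACATCCAAGAAGCCT rose the most, from 0.803 ± 0.414 to 129 ± 32.4 rpm (log2 7.09, SE 0.41, edgeR adjusted p = 4.74e-13). It was followed by TCAAGAAAACTTGAACGGCCT (6.95), the miR319 form TTGGACTGAAGGGAGCTCCCT (5.52) and CCTTGGCTTGGCTCGCGGGCACC (4.96). Without SG NEC replicate 3 these 4 were at 6.14, 6.06, 4.74 and 4.31 and TTCTCGGACCAGGCTTCATTCCCC at 4.01, and without SG NEC replicate 1 the last 3 of the 4 were at 6.26, 4.63 and 4.22. In Cabernet Sauvignon TGAAGAACATCCAAGAAGCCT was at 4.56 without CS NEC replicate 1 and 6.33 without replicate 3.

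The largest falls in Cabernet Sauvignon were of tags that all but vanished from EC. With 0 reads in EC against 1300, 1247 and 1137 in NEC, ACAAGGGAAGGGTCGCTATTAGGC was at least 316-fold lower, GCCTGTTGAGCTCACCTTGTACCC at least 303-fold lower and CAAGGGAAGGGTCGCTATTAGGC at least 276-fold lower, against a floor of 3 reads over the group. With 1 read in EC, TGTTGAGCTCACCTTGTACCC had a ratio of 1222 between NEC and EC (95% counting interval 219 to 48308), and CGGGATCGGACATTTGATGAA, with 2 reads, one of 333 (91.9 to 2755). This last tag also fell the most in Sangiovese, from 38.9 ± 4.61 to 0.205 ± 0.161 rpm (log2 -7.89, SE 0.41). The other large falls in Sangiovese were CGGAGAAGACACAATGGAGCT (-6.33) and 3 tags that start like miR393, TCCAAAGGGATCGCATTGATT (-5.66), TCCAAAGGGATCGCATTGATTTT (-5.40) and TCCAAAGGGATCGCATTGATTC (-5.19). In the order given, these 5 were at -8.54, -7.58, -6.92, -6.67 and -6.31 without SG EC replicate 3 and at -8.50, -7.04, -6.30, -6.08 and -5.84 without SG NEC replicate 3. The first 2 were at -8.58 and -6.92 without SG NEC replicate 2, and the last 3 at -6.31, -6.01 and -5.82 without replicate 1. Of the most abundant tag of each family, 10 rose and 9 fell in Cabernet Sauvignon and 10 rose and 11 fell in Sangiovese, among 25 tested.

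edgeR called 18223 of the 34827 tags in Cabernet Sauvignon (10740 higher, 7483 lower) and 24327 in Sangiovese (16003 higher, 8324 lower). Of these, 8833 rose in both cultivars, where independent lists would share 4935, and 5179 fell in both, where they would share 1789. Relative to total reads, TMM shifted the tags by log2 -0.64 in Cabernet Sauvignon and -0.19 in Sangiovese, and with total reads 15054 tags were higher and 5009 lower in Cabernet Sauvignon, with 78 called tags turned. With lane as a covariate 6367 tags were called in Cabernet Sauvignon. Within lane 7 there were 27148 calls in Sangiovese, over tags filtered anew, so this count is not comparable with 24327. Of the 24304 main calls tested there, 22513 were kept in the same direction.

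**Figure D4:**
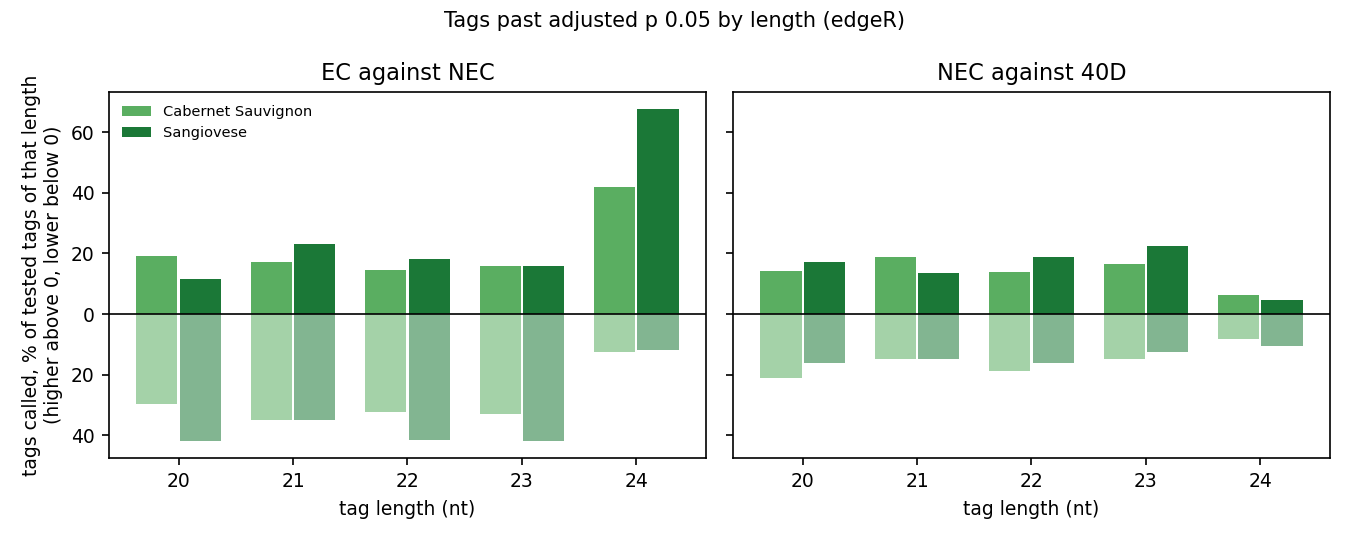
Percent of tested tags of each length (x, nt) that edgeR called higher (bars above 0) or lower (bars below 0), for EC against NEC and for NEC against 40D in Cabernet Sauvignon (light) and Sangiovese (dark). The highest bars are those of 24 nt tags in EC, at 42.0% and 67.7%. For NEC against 40D, 6.39% and 4.57% of the 24 nt tags are higher, and 8.24% and 10.6% are lower. Tags found mainly in EC pass the filter through EC, so the heights of both sets of bars are partly set by the filter.

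The comparison of EC with callus at 40 days asked how the embryogenic line differs from young, undifferentiated callus. The families miR156 (log2 4.03 in Cabernet Sauvignon, 3.16 in Sangiovese), miR159 (3.24 and 2.03), miR319 (2.26 and 3.31) and tasiARF (5.27, or 5.94 without CS 40D replicate 2, and 2.55) were again higher in EC. The strongest falls in both cultivars were of miR393 (-8.36, SE 1.14, and -6.05, SE 0.99, in Sangiovese) and miR827 (-5.74, SE 0.53, and -4.76, SE 0.44). The miR393 values were -7.71 and -8.96 without CS EC replicate 1 or 3, and -7.54 without SG EC replicate 3. For miR827, a CS EC library held 1 to 5 reads, and the family was not kept with exact matches. In Cabernet Sauvignon miR394 (4.65) and miR535 (2.99) rose as well, and miR395 was at least 54.8-fold higher, with 0 reads in 40D. Of its 106 reads in EC, 88 were in CS EC replicate 1, without which the bound was 14.5-fold. By contrast miR482 rose by 1.11 in Cabernet Sauvignon (0.31, adjusted p 0.317, with total reads) and fell in Sangiovese (adjusted p = 7.93e-07), where it did not pass with no filter on low counts (-0.55, adjusted p 0.240) or with starts within 3 nt (-0.54, adjusted p 0.0509). In Sangiovese miR162 (-2.95), miR398 (-2.46), miR167 (-2.83) and miR3634 (-1.34) fell, but miR3634 was at -0.062 with no filter, -0.051 with starts within 3 nt and -0.69 with exact matches, none past 0.05. With no filter miR166 (-0.74 to 0.54) and miR168 (-1.11 to 0.16) moved by a similar amount. A common shift in the scaling of SG 40D would give this, so the sizes of the other Sangiovese changes against 40D can hold the same shift.

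edgeR called 11 families higher and 7 lower in Cabernet Sauvignon and 9 higher and 12 lower in Sangiovese. The families shared were 8 that rose (3.54 for independent lists) and 6 that fell (3.00). TMM shifted families by log2 0.81 and -0.24 and DESeq2 by 0.64 and 0.51 relative to total reads; total reads gave 9 higher and 13 lower in Cabernet Sauvignon, and DESeq2 11 and 8 in Sangiovese, where 1 called family turned. With starts within 3 nt, 4 called families turned in Sangiovese, and miR166 (1.03) and miR171 (1.28) passed in the opposite direction. Among tags, 10668 were higher and 7205 lower in Cabernet Sauvignon and 14589 and 7753 in Sangiovese (15041 and 4751 under DESeq2). Of the 24 nt tags, 45.5% and 63.5% rose, shares that are again partly set by the filter. In Cabernet Sauvignon both groups were on lane 8. In Sangiovese the 40D libraries were on lane 8 with 1 EC library, too few for a value within the lane, and lane as a covariate gave 18322 tags.

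The comparison of NEC with callus at 40 days asked what sets older callus without embryogenic competence apart. The clearest change was of miR827, which fell in both cultivars (log2 -4.38, SE 0.45, edgeR adjusted p = 9.31e-07, in Cabernet Sauvignon and -3.75, SE 0.42, adjusted p = 1.52e-06, in Sangiovese). Its most abundant tag had 1 substitution, and the family was not kept with exact matches. Next came miR171 (-2.76 and -2.60), which passed in neither cultivar with starts within 3 nt (-0.89 and -0.51) or exact matches (-1.68 and -1.74), nor in Sangiovese with no filter (-1.40). In Cabernet Sauvignon miR164 (-2.30; -2.93 without CS NEC replicate 1), miR167 (-2.12), miR166 (-2.01) and miR403 (-1.42) fell, and miR396 rose by 2.34 and miR535 by 1.33. Of these, miR403 did not pass under DESeq2 (-0.54), with no filter (-0.84) or with exact matches (-0.11), and miR164 (-0.92) and miR167 (-0.68) did not pass with exact matches. With lane as a covariate miR164 (-2.01) and miR535 (1.33) did not pass. The fall of miR166 turned to 0.54 with reads that start up to 3 nt from the reference. In Sangiovese miR397 (-1.96), miR482 (-1.54), miR398 (-1.53), miR408 (-1.33), miR167 (-1.43) and miR3634 (-1.28) fell. There miR166 (adjusted p = 0.0019) and miR168 (-0.75) turned under DESeq2 (0.056 and 0.29), with no filter on low counts (0.25 and 0.49) and with starts within 3 nt (0.49 and 0.47).

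edgeR called 5 families higher and 13 lower in Cabernet Sauvignon and 0 higher and 12 lower in Sangiovese (0 higher at an unadjusted p under 0.05). Relative to total reads, TMM shifted the families by log2 0.15 and -0.40 and DESeq2 by 0.98 and 0.65, and DESeq2 called 9 higher and 5 lower in Cabernet Sauvignon and 2 higher and 3 lower in Sangiovese, with 1 and 3 called families turned. The abundant miR3634, which TMM held nearly constant between all other groups, was -0.89 in Sangiovese under total reads and -0.23, not passed, under DESeq2, so the falls against SG 40D depend on the scaling. In Sangiovese 3 of the 12 calls were kept under DESeq2 (miR827, miR171 and miR397), 1 with no filter (miR827), 1 with starts within 3 nt and 0 of 11 with exact matches. In Cabernet Sauvignon 10 of 18 were kept under DESeq2, 8 with starts within 3 nt and 5 of 16 with exact matches. Without CS NEC replicate 1, or without CS 40D replicate 1, 11 families were called in Cabernet Sauvignon. Among tags, 3748 were higher and 4198 lower in Cabernet Sauvignon and 3551 and 4352 in Sangiovese, with 2205 and 7432, and 2908 and 5535, under total reads. All NEC libraries were on lane 7 and all 40D libraries on lane 8, and with lane as a covariate 837 and 449 tags and 7 and 7 families were called.

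Between the cultivars, 4 of the 28 families differed in EC with TMM factors, and 13 with total reads as library size. There SG EC had less miR482 (log2 -2.11, SE 0.21, edgeR adjusted p = 5.02e-07) and less miR394 (-3.18, and -2.68, adjusted p 0.0626, with lane as a covariate) than CS EC, and more miR827 (2.19). A CS EC library held 1 to 5 miR827 reads, and neither miR827 nor miR399 was kept with exact matches. Family miR399 had 1 read in CS EC against 75 in SG EC, a ratio of 37.7 (95% counting interval 6.56 to 1507), and its call was lost without CS EC replicate 1 or replicate 3 (3.50 at the lowest); its 1 read was in replicate 2. In NEC, Sangiovese had more miR166 (2.20, but -0.057 with starts within 3 nt), miR827 (1.85), miR403 (1.10, but -0.21 with exact matches), miR167 (1.66) and miR3627 (3.52), and less miR319 (-1.44). The call of miR3627 was lost in all 6 runs without 1 library (3.00 at the lowest and 4.77 without CS NEC replicate 1), and those of miR167 (1.57) and miR403 (0.91) without CS NEC replicate 1. With exact matches 1 of 5 calls in NEC was kept, and under DESeq2 4 of 6.

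At 40 days, Sangiovese had more miR3634 (1.29), tasiARF (2.22; 2.89 without CS 40D replicate 2), miR396 (1.93), miR535 (1.38), miR398 (1.29) and miR166 (1.19, but -0.0090 with starts within 3 nt), and less miR319 (-1.31). It also had more miR156 (1.04), miR827 (1.21) and miR482 (0.80), and with no filter on low counts these turned to -0.22, -0.054 and -0.46 and miR166 to -0.080. Under DESeq2 miR3634 (0.51), miR535 (0.59) and miR398 (0.55) did not pass, and with no filter neither did these (0.022, 0.12 and 0.031), tasiARF (0.98) or miR396 (0.68). Of the 16 calls, 4 were kept under DESeq2, 2 with no filter, 2 with starts within 3 nt and 1 of 14 with exact matches. The call of miR156 was lost without CS 40D replicate 3 or SG 40D replicate 3 (0.83 at the lowest), and that of miR827 without CS 40D replicate 2 or 3 (0.95).

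edgeR called 2 families higher and 2 lower in EC of Sangiovese against Cabernet Sauvignon, 5 and 1 in NEC and 14 and 2 at 40 days. Under total reads the split in EC was 11 and 2, and under DESeq2 it was 3 and 3 in NEC and 2 and 2 at 40 days. TMM shifted the families by log2 -0.82, -0.32 and 0.23 and DESeq2 by -0.67, -0.87 and -0.53 relative to total reads. Without CS NEC replicate 1, 3 families were called in NEC, and without CS 40D replicate 3, 8 were called at 40 days.

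The last comparison asked whether EC and NEC differ by the same amount in both cultivars. The difference was smaller in Sangiovese for miR482 (log2 -2.25, SE 0.29, edgeR adjusted p = 1.67e-05) and miR166 (-2.07, SE 0.33, adjusted p = 0.000137). That of miR166 turned to 0.31 (adjusted p 0.586) with reads that start up to 3 nt from the reference, and neither passed with no filter on low counts or with exact matches. Of the 28 families, edgeR called 0 higher and 2 lower (at an unadjusted p under 0.05, 1 and 7), and DESeq2 and total reads each gave 1 higher and 2 lower. For tags, edgeR called 2546, 1788 with a higher signed log2 fold change in Sangiovese and 758 with a lower one; a higher value can be a weaker fall. With total reads the split was 1168 and 2087, and with lane as a covariate 1209 tags were called. By length, 918 of the 24 nt tags (4.70% of those tested) had a higher signed value in Sangiovese and 155 a lower one. At 21 nt the counts were 513 (9.13%) and 155. At 20 and 23 nt more tags had a lower value (161 and 134) than a higher one (61 and 103).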

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

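All tests of the miR166 form below were chosen after its values had been seen; the splits of the libraries were planned.

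The difference between EC and NEC differed between the cultivars for miR166 (log2 -2.07, Sangiovese against Cabernet Sauvignon). In CS NEC a miR166 form that starts 2 nt upstream, TCTCGGACCAGGCTTCATTCC, exceeded the reference form TCGGACCAGGCTTCATTCCCC with a ratio of 4.97 ± 1.35 (SD, n = 3), against 0.442 ± 0.0386 in CS EC and 0.283 ± 0.0369 in SG NEC. Lane is argued against, since no SG NEC library on the same lane had a ratio above 0.324. A general upstream start of reads is excluded as well, as at most 0.0289% of the reads of the other families started there in a CS NEC library. The ratio was at most 0.468 in the CS EC and 40D libraries, which argues against a cultivar variant that acts alike in all tissues. A variant in a precursor expressed mainly in NEC is not excluded by these values. A candidate explanation is a change in how the miR166 precursors are processed or which of them are expressed in this callus, a hypothesis found on these data and not tested here, as reads were not placed on the precursors, and a difference between the cultivars' NEC lines stays open and untested.

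For miR482 the difference between EC and NEC also differed between the cultivars, by log2 -2.25. Of 100 splits of the 12 EC and NEC libraries, the real one included, 12 gave at least the real count of 2 families, with 6 as the highest other count, so chance cannot be excluded for that count. The split with 6 exchanged the cultivars within NEC, so that differences between the cultivars entered it. The number of tags whose difference between EC and NEC differed between the cultivars was 2546. Here 3 of 100 splits gave as many, the real one included. The splits exchange cultivar labels within a tissue, so differences between the cultivars entered the other splits. The share therefore cannot decide whether chance gave the count. The highest other count, 6388, came from a split that exchanged the cultivar of most NEC libraries.

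Among the named tags, 5 differed between the cultivars in this way. ACAAGGGAAGGGTCGCTATTAGGC had a fitted log2 difference between the cultivars of 9.24, CAAGGGAAGGGTCGCTATTAGGC of 8.99, GCCTGTTGAGCTCACCTTGTACCC of 8.96 and TGTTGAGCTCACCTTGTACCC of 7.92. These fitted sizes rest on 0 or 1 read in CS EC and depend on the prior count; in Sangiovese the same tags fell by 2.91, 2.96, 3.15 and 2.62. CCTTGGCTTGGCTCGCGGGCACC rose by 1.66 in Cabernet Sauvignon and by 4.96 in Sangiovese, a difference of 3.30.

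Reads over 30 nt were outside the planned comparisons and were tested only after their values had been seen. A 33 nt fragment from the 5' end of a glutamate tRNA made up 2.73% ± 0.395 of all reads (SD, n = 3) in CS NEC and 2.63% ± 0.252 in SG NEC, against 0.218% to 0.385% as group means in EC and 40D. A 36 nt fragment from the 5' end of a histidine tRNA made up 0.671% ± 0.199 in CS NEC and 0.440% ± 0.0111 in SG NEC, against 0.0503% to 0.160% as group means elsewhere.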

How the results depend on the processing

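Matching with starts within 3 nt and the joint removal of abundant tags and structural RNA were tests chosen after the data were seen. All size class results kept direction and call under every alternative (the ratio of NEC against 40D was -0.20 without the 20 most abundant tags), except the difference of the 24 to 21 nt ratio between the cultivars (main value -0.11). It was 0.29 without the 20 most abundant tags, 0.285 without these and structural RNA, and -0.38 to 0.065 with 1 library left out (-0.38 without CS EC replicate 1, exact permutation, past 0.05, and 0.065 without CS EC replicate 2). Counts of families called moved by more than 1.5 times as follows. In SG NEC against 40D (12), DESeq2 gave 5, total reads 7, no filter 3, lane 7, exact matches 0 and starts within 3 nt 3. Cultivars at 40 days (16) gave 4 under DESeq2, 9 under total reads, 2 with no filter, 1 with exact matches, 2 with starts within 3 nt, and 8 to 18 with 1 library left out. In CS NEC against 40D (18), lane gave 7, exact matches 9, starts within 3 nt 8, and leaving out 1 library 11 to 17. Total reads gave 13 for the cultivars in EC (4); no filter gave 3 and leaving out 1 library 3 to 5 for those in NEC (6). Lane gave 12 for CS EC against NEC (19), and exact matches 12 for SG EC against NEC (19); with exact matches 8 of 16 calls of CS EC against NEC kept direction and call. The difference between cultivars (2) was 0 with no filter, where 32 families were tested, and 1 with exact matches. With the low filter, which tested 183177 tags, calls rose to 33623 and 84324 for EC against NEC (CS and SG) and 51988 and 82775 for EC against 40D. With lane as a covariate they were 6367 for CS EC against NEC, 837 and 449 for NEC against 40D (CS and SG) and 1209 for the difference between cultivars, a fit in which 1 SG EC library ties the lanes within a group. Signs of named families turned as follows, none past 0.05; of unnamed ones, miR166 (1.03) and miR171 (1.28) turned past 0.05 in SG EC against 40D with starts within 3 nt. With exact matches, in CS EC against NEC, miR390 was -0.23 and miR408 -0.22; in CS NEC against 40D, miR408 was 0.18 and miR482 0.64; in NEC between cultivars, miR403 was -0.21. With starts within 3 nt, miR166 was 0.54 in CS NEC against 40D, 0.49 in SG NEC against 40D (miR168 0.47), -0.057 between cultivars in NEC, -0.0090 at 40 days (miR482 -0.19), and 0.31 for the difference between cultivars. Under DESeq2, miR166 and miR168 were 0.056 and 0.29 in SG NEC against 40D. With no filter they were 0.25 and 0.49, and between cultivars at 40 days miR156 was -0.22, miR166 -0.080, miR482 -0.46 and miR827 -0.054. The cause was not tested directly, except that exact matches tested 24 families in place of 28. All turns with no filter were in comparisons with SG 40D, and the families that turned moved by similar amounts. Between cultivars at 40 days, miR156 went from 1.04 to -0.22, miR482 from 0.80 to -0.46 and miR827 from 1.21 to -0.054. In SG NEC against 40D, miR168 went from -0.75 to 0.49. A common shift in the scaling of SG 40D would give this, which argues against separate changes of these families. Of 1026 values of named families and tags under alternatives, 859 kept direction and call, 147 lost the call and 20 turned. Replicate numbers did not pair the libraries: the correlations of deviations of same-numbered libraries ranged from -0.57 to 0.56, and no comparison had every library correlate best with its own number. With the replicate block, families called were 19 for CS and SG EC against NEC alike, 15 for CS NEC against 40D and 5 for NEC between cultivars, where miR3627 missed the threshold, and tags called were 17699 and 24015 for EC against NEC. The 24 nt windows were not run, as no genome sequence was used here.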

Other observations

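The tests of the first base, of reads over 30 nt and of the most abundant tag were chosen after the values had been seen. Those of lane and of scaling partly used alternatives fixed beforehand, but their use against these explanations was set after the values had been seen. Tests without abundant tags, per family read and of the splits were planned.

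The first base of 24 nt reads differed between the tissues. Adenine led 50.2% ± 2.50 (SD, n = 3) of them in CS EC and 50.8% ± 0.263 in SG EC, against 32.3% ± 2.80 in CS NEC, 34.9% ± 1.28 in SG NEC, 32.8% ± 1.85 in CS 40D and 36.6% ± 0.962 in SG 40D. EC exceeded NEC by 16.9 percentage points (exact permutation within cultivars, p = 0.005, the smallest possible, adjusted p 0.01 over 10 tests), and by 15.9 within lane 7 in Sangiovese. Distinct 24 nt sequences made up 57.8% ± 5.09 of those of 18 to 30 nt in CS EC and 63.9% ± 0.710 in SG EC, against 29.7% ± 3.27 and 33.1% ± 3.18 in NEC.

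NEC carried more of other classes. Reads over 30 nt made up 44.8% ± 4.32 of all reads in CS NEC and 44.0% ± 2.32 in SG NEC, against 26.0% ± 0.870 and 31.3% ± 8.03 in EC (difference -15.8 percentage points, exact permutation p = 0.005, adjusted p 0.01). This share followed lane: in SG EC the lane 8 library differed from those on lane 7 by -13.4 percentage points, and within lane 7 SG EC differed from SG NEC by -8.32, so lane is not excluded as its cause. The most abundant tag, CCCAGTCCCGAACCCGTCGGC, matched no family or structural reference (these hold no large rRNA, so an rRNA origin was not tested) and made up 17.8% ± 1.94 of 18 to 30 nt reads in CS NEC and 12.6% ± 0.531 in SG NEC, against 6.68% ± 1.13 and 2.93% ± 0.332 in EC (-10.4 percentage points, exact permutation p = 0.005, adjusted p 0.01). For the 5' fragment of glutamate tRNA the difference was -2.38 percentage points, with the same p and adjusted p. Within lane 7 in Sangiovese, EC differed from NEC by -9.44 percentage points for the tag and -2.17 for the tRNA fragment.

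The higher 24 nt share of EC was set against technical explanations. Lane argues little for Sangiovese, where EC exceeded NEC by 24.7 percentage points within lane 7, and a few abundant tags do not account for it, as the log2 difference of the 24 to 21 nt ratio was 1.78 without the 20 most abundant. As to dilution of NEC by breakdown fragments, 24 nt reads per read of the families other than miR166 were higher in EC by at least 1.94 on the log2 scale in both cultivars. Most of these family reads were of miR3634 (144473 of 166438 in CS NEC replicate 1, 194134 of 230761 in SG NEC replicate 1). In the fit over tags its most abundant tag was at log2 -1.37 in Cabernet Sauvignon and -0.37 in Sangiovese. The value thus argues against dilution only as far as this 1 family is a steady measure. For Cabernet Sauvignon lane and tissue cannot be told apart, and the lane 8 library of SG EC, -0.119 percentage points from those on lane 7, is 1 library and excludes nothing. A higher output of 24 nt small RNA in embryogenic callus, or a lower one in NEC, is a hypothesis that was not tested here, as no absolute amounts were measured, and the Cabernet Sauvignon part stays open.

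The 14 families that changed in the same direction in both cultivars were tested against scaling and lane. All 9 with a log2 change of at least 2 in both cultivars (miR156, miR159, miR319, miR393, miR394, miR395, miR397, miR845 and tasiARF) kept direction and call under DESeq2 size factors and under total reads. The cut of 2 exceeds the shifts between the scalings (0.66 for TMM and -0.34 for DESeq2 relative to total reads in Cabernet Sauvignon). It thus largely fixed that no direction turned, and the values show only that the calls were kept. Of the 5 others, 2 kept them, so the choice of scaling may account for the rest. Within lane 7, 12 of the 14 kept direction and call in Sangiovese, which argues against lane for those 12 there, while miR398 and miR827 lost the call. With lane as a covariate 9 of the 14 kept direction and call in both cultivars. With exact matches as well, 6 of the 14 kept them (miR156, miR159, miR319, miR393, miR394 and miR395), and miR393 did not pass with lane as a covariate.

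For each comparison of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. In every one the real split ranked 1 of the 10 by its number of calls. For families the real counts were 19, 19, 18, 21, 18 and 12 in the comparisons of tissues (EC against NEC, EC against 40D and NEC against 40D, Cabernet Sauvignon before Sangiovese), with 0 as the highest of the other splits in each. Between cultivars they were 4 in EC (highest other 3), 6 in NEC (highest other 0) and 16 at 40 days (highest other 7). For tags they were 18223, 24327, 17873, 22342, 7946 and 7903 in the same order of tissues, with 0 as the highest other in each.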
